A study of Mus musculus with 6 samples.

How the data were processed

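Total RNA of neural stem cells from mice was hybridised to 6 Affymetrix arrays, 1 sample per array, 3 from young mice of 6 weeks and 3 from old mice of 9 months. Per the labels' protocols, RNA was extracted with the NucleoSpin XS kit, then fragmented and labelled with biotin using the NuGEN Encore Biotin module. The deposited values are log2 expression levels per probe set, made with GCRMA per the submitters' processing notes. GCRMA corrects background by probe sequence, normalizes between arrays and sums up the probes of a probe set. Its version, the scanner software and the chip definition are not given in the sources used here. The log2 scale was read from the values, which share a lowest value of 2.14 and have about the same quartiles on every array. GCRMA sets dim probe sets close to one value, so a large change out of that floor has an uncertain size and replicate spread there is understated. Scanner files and detection calls were not used here.

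Probe sets were named from the platform annotation, with symbols updated by Entrez identifiers through RefSeq gene names of assembly GRCm38.p6. Of the identifiers 99.4% matched, and 0 symbols changed. After 64 control probe sets were left out, 34945 probe sets had 1 symbol, 932 had several and 9160 were unnamed here. Genes were named only from probe sets with 1 symbol. The genome build behind the array is not given in the sources used here, so no coordinates are printed, and chromosomes and the order of genes come from that assembly.

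Probe sets above log2 4 on at least 3 of the 6 arrays were kept, 19858 in all, of which 17803 had 1 symbol. Old and young arrays were compared per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided), with Benjamini-Hochberg adjustment over all kept probe sets and a threshold of 0.05. The moderated variances had 4 residual and 1.47 prior degrees of freedom. A gene stands for its kept probe set with the highest mean over the 6 arrays, and probe sets that disagree in sign at an unadjusted p under 0.05 are said to disagree. Genes were tested as lists with camera, with a preset correlation of 0.01 and, beside it, an estimated correlation, and with fry, which asks whether a list moves at all and does not compare it with other genes. Of the 50 lists fixed, 42 had at least 5 measured genes and were tested, with adjustment over these. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

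The groups, the test, the filter, the lists and the rule for named genes were chosen before the data were examined. By that rule the text could name, leaving out placeholder symbols, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose ages do not overlap, up to 4 members of each list with the smallest p, and Lmna, Lmnb1, Lmnb2, Sun1, Sun2, Nes, Sox2, Gfap, Mki67, Cdkn1a and Cdkn2a. It led to 199 genes, of which a part is named. Levels of genes under the filter are given for a few markers, picked after their values were seen.

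The alternatives were other filters, quantile normalization of the deposited values again, centring each array on its median, the replicate number as a block, array weights, leaving out each array, eBayes with trend and robust options, other thresholds and the mean of each gene's probe sets. The tests were tried on simulated data with 19858 probe sets for old against young. The probe set test found 35.8% of changes of log2 0.5, 68.7% of log2 1 and 86.4% of log2 2, with 4 false calls among the unchanged probe sets, or 3.05% of all calls. Only 67, 67 and 66 probe sets were changed by these amounts, while 36.6% of all were called in the data. The adjusted threshold thus fell at another unadjusted p, so these shares do not say how many real changes the reported comparison found. For old against young with 10050 simulated genes, the list test called the 1 list shifted by log2 -0.5 and 0 of the others. The simulated genes varied independently of each other, so this trial does not test the preset correlation. In the data the estimated correlation was 0.69 for the mitosis list.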

Results

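Messenger RNA levels were measured on 6 arrays of neural stem cells, the cells of the brain that renew themselves and give rise to neurons and glia. The cells came from C57BL/6JRj mice, a substrain of the common C57BL/6 laboratory mouse. There were 3 samples from young mice of 6 weeks and 3 from old mice of 9 months. Each array held 45101 probe sets, and 38.3 to 40.4% of them lay at the shared lowest value, log2 2.14. Over the probe sets kept by the filter, the 3 old arrays correlated with each other at r = 0.995 in every pair. The young pairs correlated at 0.979 to 0.993, and pairs of a young and an old array at 0.915 to 0.944. These r values are across probe sets, which are not independent replicates. The first principal component held 83.2% of the variance and separated the ages, and young replicate 2 stood apart on the second, which held 9.93%. No 2 arrays held identical values. The number of arrays limits the precision. The labels do not say whether the replicates came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical.

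The comparison of old with young cells asked which transcripts differ with age in cells of this type, in a series on how age is shared out when mammalian neural stem cells divide. Old cells held high levels of genes that were near background in young cells, among them the collagen chaperone Serpinh1, the metalloproteinase inhibitor Timp1 and the lipoprotein lipase Lpl. Young cells held high levels of genes that were near background in old cells, among them the mitochondrial creatine kinase Ckmt1, the nicotinic receptor subunit Chrna4 and the transcription factor Nkx2-2. By camera with a preset correlation of 0.01, genes of neuroblasts, mitosis and the hypoxia response were lower as groups in old cells. The measured genes of the interferon response and the measured secreted factors tied to senescence were higher, with 17 and 16 further members under the filter. All of these calls were lost with a correlation estimated from the data. The interferon call was also lost without genes on chromosomes 10 and 11, though the median of the 8 members left was 1.17 against 1.22 for all 11. The call for secreted factors was lost without the filter. In limma, 7268 of 19858 probe sets changed at an adjusted p under 0.05, or 36.6%, with 3995 higher and 3273 lower in old cells. At an unadjusted p under 0.05 there were 9430. These calls covered 4076 of 10050 named genes, 2215 higher and 1861 lower, with a median fold of 1.48. The 3 old arrays all lay on one side of the 3 young arrays for 55.3% of the probe sets, where chance gives 10%. Without old replicate 2, the count of lower probe sets was 2177, the lowest on leaving out 1 array.

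By fitted values 148 genes differed at least 16-fold, 64 higher and 84 lower in old cells. No detection calls were used here, so log2 4 stands in for background throughout, and a gene under it on every array of one age is given as at least N-fold, computed against that level. A changed gene with its mean under log2 4 at one age, but not every array, is given as at least N-fold against its highest array of that age. Of the 148 genes 62.8% lay under log2 4 on every array of one age. With these 62.8% at their bound, 103 genes differed at least 16-fold, 42 higher and 61 lower. The 61 include a gene whose mean, but not every array, lay under log2 4 in old cells. Against its highest old array it fell at least 10.3-fold. Pcp4l1 rose from 2.44 ± 0.16 in young cells to 12.25 ± 0.11 in old cells (log2, SD, n = 3), which was at least 305-fold (adjusted p = 7.83e-07). Serpinh1 rose from 3.33 ± 1.06 to 12.83 ± 0.075, which was at least 336-fold (adjusted p = 0.000236), and its second probe set rose as well (adjusted p = 2.79e-07). The short-chain dehydrogenase Dhrs4 rose at least 234-fold, Timp1 at least 233-fold and Lpl at least 116-fold. Cadps2, which acts in the release of dense-core vesicles, rose at least 97.0-fold. The peptidase Cpq rose at least 88.5-fold, the lymphocyte inhibitory receptor Btla at least 84.2-fold and the heparan sulfate sulfotransferase Hs3st1 at least 68.2-fold. The mitotic cyclin Ccnb2 rose at least 60.8-fold, by 1 probe set. Ank3, the ankyrin of the axon initial segment, rose at least 31.7-fold, and its other 2 kept probe sets rose as well. Serpinb11, a member of the serpin family, rose at least 26.8-fold.

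Among the falls, Ckmt1 went from 12.36 ± 0.077 in young cells to 3.36 ± 0.91 in old cells (log2, SD, n = 3), which was at least 262-fold (adjusted p = 0.000174). Chrna4 fell at least 234-fold by its brightest probe set (adjusted p = 6.24e-07), while its other kept probe set, with a log2 change of -1.10, did not pass (adjusted p = 0.0774). Tmem35a, a chaperone of nicotinic receptors, had a log2 change of -7.90. Nkx2-2, a transcription factor of the oligodendrocyte lineage, fell at least 91.2-fold, and the lysosomal protease Ctsz at least 71.5-fold. Of the membrane and adhesion proteins of neural cells, Tenm3 fell at least 62.5-fold, Pcdh17 at least 53.5-fold and Slitrk5 at least 38.8-fold. Cacng5, an auxiliary subunit of glutamate receptors, fell at least 58.3-fold and the membrane protein Itm2a at least 62.2-fold. Ugt8a, which makes the galactolipids of myelin, fell at least 49.6-fold. Neurod4, a proneural transcription factor, fell at least 38.7-fold. The 24 genes named in these paragraphs had adjusted p of at most 0.000879. All 18 hybridisation control probe sets, which read RNA of fixed amount added to each array, were lower on every old array than on every young array. Their mean was 13.24 ± 0.28 in young and 12.28 ± 0.098 in old arrays (log2, SD, n = 3), a difference of -0.96 with an exact permutation p of 0.1 (two-sided), the smallest that 3 against 3 can give. The actin control, read near the 3' and the 5' end of the transcript as a sign of RNA quality, had a 3' minus 5' value of 0.62 ± 0.043 in young and 0.69 ± 0.036 in old arrays (log2, SD, n = 3), higher on every old array than on every young one (exact permutation p = 0.1). The same measure did not part the ages for Gapdh (exact permutation p = 0.3) or the transferrin receptor (exact permutation p = 0.5). These differences run along with every gene group described here, since all compare the same 6 arrays.

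**Figure D1:**
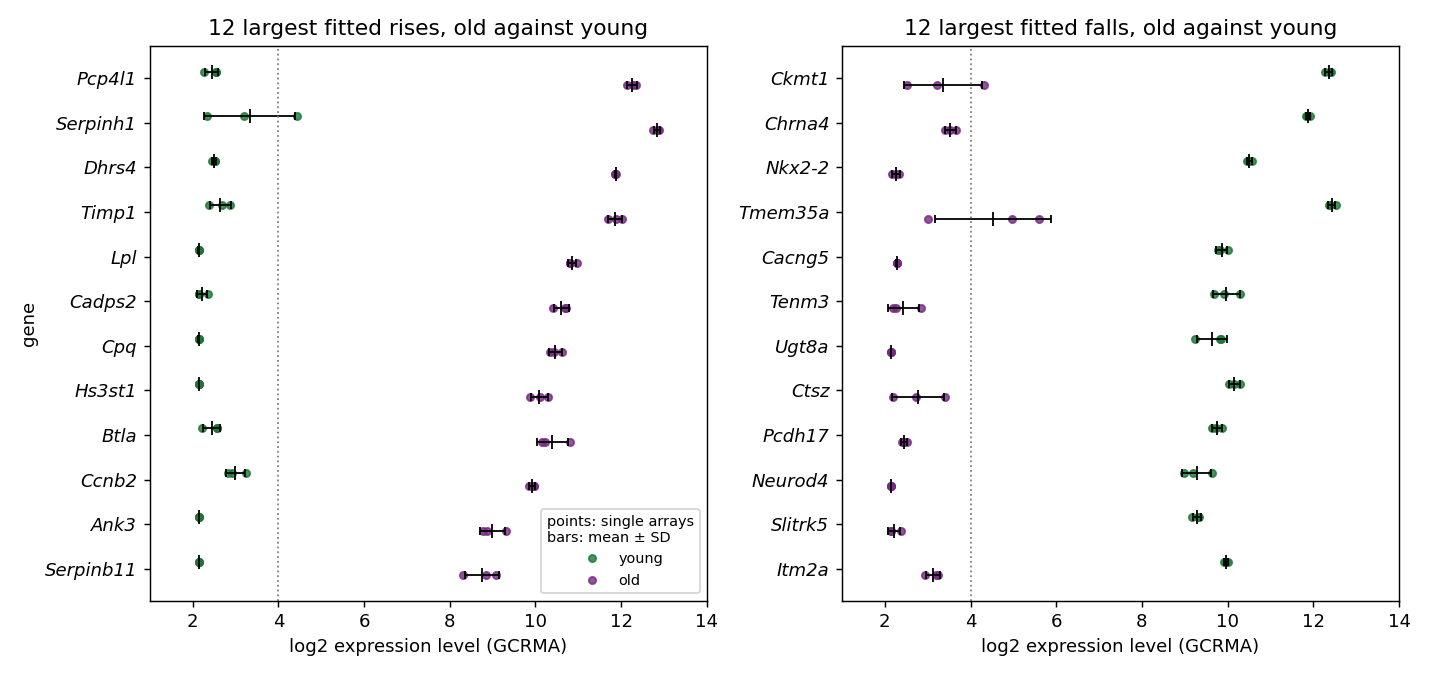
Expression level (log2, GCRMA) of the 12 genes with the largest rise and the 12 with the largest fall in old cells by fitted values, each point 1 array, with the mean and SD of 3 arrays as a bar and a dotted line at log2 4. In 11 of the 12 rises the 3 young arrays, and in 10 of the 12 falls the 3 old arrays, lie under that line.

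Genes fixed as groups were then compared with all other measured genes, 42 lists with at least 5 measured genes each. By camera with a preset correlation of 0.01, 10 lists passed, 7 lower and 3 higher in old cells. With a correlation estimated from the data, camera passed 0 lists (smallest adjusted p = 0.573), with 2 lists at an unadjusted p under 0.05, and fry passed 32 lists in one direction and 41 in either direction. Counts of members are adjusted over all probe sets, and the count adjusted over the list alone follows wherever it differs. They are to be read against all 10050 genes, of which 2215 rose and 1861 fell. Below, a gene's change given without the word fold is on the log2 scale.

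In the list of neuroblasts and intermediate progenitors, 6 of 8 measured members fell and none rose (8 fell adjusted over the list alone). Tubb3, the neuronal tubulin, fell at least 43.3-fold, and Dlx2, a transcription factor of interneuron progenitors, had a log2 change of -3.71. The proneural factor Neurod1 fell at least 16.6-fold, and Sox4 had a log2 change of only -0.33. The list passed as lower (median -0.33, adjusted p = 0.000254, and adjusted p = 0.573 with an estimated correlation). Another 13 members were under the filter, among them the migrating neuroblast gene Dcx, which reached 5.37 on a young array and stayed at 2.14 on the old arrays, and Stmn2, at 2.14 on all 6. Of the 10 measured neuron genes 4 fell and 1 rose (5 fell and 1 rose adjusted over the list alone), and the list did not pass (adjusted p = 0.382). The RNA-binding protein Elavl3 had a log2 change of -3.17 and the synaptic vesicle protein Syn1 -0.82, while Gad1, which makes the transmitter GABA, rose by 1.58.

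Stem cell and glial markers went both ways. Of 22 genes of neural stem cells and radial glia, 3 rose and 7 fell (3 and 8 adjusted over the list alone), and the list did not pass (adjusted p = 0.197). The Notch target Hes5 fell at least 13.7-fold, Id4 had a log2 change of -1.49, Sox1 of -0.73 and the intermediate filament Nes of -0.46, while Thrsp, a regulator of lipid synthesis, rose by 1.91. Sox2 (-0.14, adjusted p = 0.122) and Gfap (0.31, adjusted p = 0.446) did not pass. In the Notch pathway 6 of 14 genes fell and 3 rose (adjusted p = 0.172), and the ligand Dll3 fell at least 1.75-fold. Of 22 astrocyte genes 9 rose and 4 fell (10 and 4 adjusted over the list alone), and the list did not pass (adjusted p = 0.405). The calcium-binding protein S100b rose by 2.93 and the gap junction protein Gja1 by 1.36, against -3.35 for Ntsr2 and -0.59 for Fgfr3. Of 11 genes of oligodendrocyte progenitors 5 fell and 2 rose (6 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.0949), although Nkx2-2 was joined by the proteoglycan Cspg4 (-1.99), Cacng4 (-2.13), Lhfpl3 (-1.94) and the growth factor receptor Pdgfra (-1.44). Of 5 genes of mature oligodendrocytes 2 rose and 2 fell (adjusted p = 0.957). Aspa, which breaks down N-acetylaspartate, rose at least 12.6-fold and Bcas1 by log2 0.93, while Ugt8a fell and the tight junction gene Cldn11 had a log2 change of -2.75. The genes of dorsal telencephalon identity did not pass (1 rose and 1 fell of 7, 2 and 2 adjusted over the list alone, adjusted p = 0.712), and of those of the ventral telencephalon 1 gene was measured, Dlx2.

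Of 33 measured genes of mitosis 28 fell and 1 rose (32 and 1 adjusted over the list alone), with a median log2 change of -0.55 (adjusted p = 9.57e-08, and adjusted p = 0.589 with an estimated correlation). Cdc25c, the phosphatase that starts mitosis, had a log2 change of -0.97, the chromokinesin Kif4 of -0.83 and the centromeric histone Cenpa of -0.71. The proliferation marker Mki67 had one of -0.54 (adjusted p = 0.0332), a call lost without young replicate 3 and without each of the old replicates. The 1 member that rose was Ccnb2. Of 32 genes of DNA replication 7 fell and 2 rose, and the list did not pass (median -0.14, adjusted p = 0.106). The primase Prim1 had a log2 change of -0.49, Gins1 of -0.43 and the helicase subunit Mcm7 of -0.36, while the uracil glycosylase Ung rose by 0.30. In DNA repair 7 of 27 genes fell and none rose (median -0.19, adjusted p = 0.0128, and adjusted p = 0.632 with an estimated correlation), with Xrcc1 at -0.94, Rad52 at -0.63, Rad50 at -0.60 and Fancd2 at -0.65. The Fancd2 call was lost without young replicates 1 or 3 and without old replicates 2 or 3. Of 21 regulators of heterochromatin and the epigenome 6 fell and none rose (median -0.24, adjusted p = 0.00256, and adjusted p = 0.573 with an estimated correlation). They included the chromatin protein Hmga2 (-1.52), the DNA demethylase Tet1 (-1.01), the Polycomb subunit Eed (-0.62) and the histone demethylase Kdm6b (-0.35).

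Genes tied to cell cycle arrest did not move as one. Among 20 cell cycle inhibitors and p53 targets 5 rose and 7 fell (6 and 8 adjusted over the list alone), and the list did not pass (adjusted p = 0.58). Cdkn2a, the inhibitor that marks senescent cells, had a log2 change of -0.71 (11.20 ± 0.088 in young and 10.49 ± 0.12 in old cells, SD, n = 3, adjusted p = 0.00243). Cdkn1a had one of -0.21 (adjusted p = 0.0352), a call lost on leaving out any 1 of the 6 arrays. Btg2 had one of -1.55, Gadd45b of -1.17 and Zmat3 of -0.56, while Ccng1 rose by 0.52. Of the secreted factors associated with senescence 8 were measured and 16 lay under the filter. Among the 16 were Il6, Il1a, Il1b and Cxcl1, at 2.14 on all 6 arrays, and Mmp3, which reached 4.28 on an old array and stayed at 2.14 on the young ones. Of the 8, 7 rose and 1 fell, and the list passed as higher (median 0.55, adjusted p = 0.00735, and adjusted p = 0.573 with an estimated correlation). Besides Timp1, the chemokine Ccl2 rose by 1.55, the metalloproteinase inhibitor Timp2 by 1.17 and the growth factor binding protein Igfbp4 by 0.45.

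The nuclear envelope and the endoplasmic reticulum were fixed as groups because the series deals with how age is shared out at division. Of 16 genes of the nuclear lamina 7 rose and 3 fell, and the list did not pass (median 0.13, adjusted p = 0.382). The A-type lamin gene Lmna rose from 10.01 ± 0.20 to 10.83 ± 0.20 (log2, SD, n = 3), a change of 0.83 (adjusted p = 0.00951), and from 6.52 to 8.02 at another probe set (adjusted p = 0.00192). The B-type lamins went the other way, with Lmnb2 at -0.39 (adjusted p = 0.0126) and Lmnb1 at -0.22 (adjusted p = 0.0297), the latter call being lost on leaving out any 1 array. Tmem201, a protein of the inner nuclear membrane, rose by 0.89, the methyltransferase Icmt, which acts on prenylated lamins, by 0.58 and Tor1aip1 by 0.46. At the other kept probe set of Tmem201 the change was 0.05 (adjusted p = 0.622). In the LINC complex, which ties the nucleus to the cytoskeleton, 0 of 6 genes passed in limma, adjusted over all probe sets or over the list alone (list adjusted p = 0.606, by camera's test higher, with the median above and the mean below 0). Sun1 had a change of 0.24 (adjusted p = 0.0571) and Sun2 of 0.33 (adjusted p = 0.0741). The nuclear pore was lower, with 10 of 25 genes falling and none rising (median -0.20, adjusted p = 0.00423, and adjusted p = 0.573 with an estimated correlation). Nup37 had a log2 change of -0.83, Nup188 of -0.57, Nup205 of -0.49 and Nup88 of -0.48.

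Chaperones and unfolded protein response genes of the endoplasmic reticulum did not pass as a group, with 7 of 23 rising and 2 falling (8 and 2 adjusted over the list alone, adjusted p = 0.248). Dnajb9 rose by 0.58 and Hyou1 by 0.37, and Edem1, which acts in the disposal of misfolded proteins, by 0.39, while the stress transcription factor Ddit3 had a log2 change of -1.45. Edem1 did not pass on the mean of its probe sets (0.14). Of 15 proteins that shape this organelle 3 rose and 5 fell (adjusted p = 0.405). The reticulon Rtn1 had a change of -0.58 and Reep1 of -0.40, Reep2 fell at least 2.43-fold, and the fusion GTPase Atl3 rose by 0.38. Of 9 septins, GTPases that form diffusion barriers, 2 rose and 2 fell (2 and 3 adjusted over the list alone). The list did not pass (adjusted p = 0.957, lower by camera's test and by the mean, with the median above 0). Septin3 had a change of -1.45 and Septin8 of -0.54, while Septin4 rose by 0.77 and Septin6 by 0.31. The probe sets of Septin6 disagreed, another having -0.40 (adjusted p = 0.059). Of 31 proteasome genes 1 rose and 1 fell, Psmd7 by 0.20 (adjusted p = 0.0488) and Psmb6 with -0.22 (adjusted p = 0.0226), both calls being lost on leaving out any 1 array other than young replicate 1. Adjusted over the list alone, limma called 0 of the 31, and the list did not pass (adjusted p = 0.521). Of 26 genes of autophagy and the lysosome 8 rose and 2 fell (9 and 2 adjusted over the list alone, adjusted p = 0.251), with the glucuronidase Gusb rising by 0.62 and Map1lc3a by 0.56. In the heat shock response 4 of 12 genes rose and none fell (adjusted p = 0.216), led by the co-chaperone Bag3, which rose by 5.61, and the small heat shock protein Hspb8, which rose by 1.39.

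Genes induced by low oxygen were lower in old cells, with 14 of 16 falling and 1 rising (median -0.50, adjusted p = 6.50e-06, and adjusted p = 0.573 with an estimated correlation). Ndrg1 fell at least 46.1-fold. Ankrd37 had a log2 change of -3.04, the mitophagy receptor Bnip3 of -1.65 and the hexokinase Hk2 of -0.91. In glycolysis 3 of 15 genes rose and 5 fell, and the list did not pass (adjusted p = 0.325), with the phosphofructokinase Pfkl at -1.87. Oxidative phosphorylation was higher by camera, with 7 of 37 genes rising and none falling (3 rose adjusted over the list alone, median 0.10, adjusted p = 0.0128, and adjusted p = 0.767 with an estimated correlation). This share of rising genes was not above that over all genes, 2215 of 10050. The complex I subunits Ndufs1 and Ndufa6 rose by 0.39 and 0.38, and Cox6c and Cyc1, of the later complexes, by 0.35 and 0.29. The call of this list was lost without old replicate 2 (adjusted p = 0.0603). The Ndufa6 call was lost without young replicate 1 or any 1 of the old replicates. Cholesterol synthesis was lower, with 11 of 20 genes falling and 1 rising (13 and 1 adjusted over the list alone, median -0.25, adjusted p = 0.00103, and adjusted p = 0.573 with an estimated correlation). Lss, which closes the sterol ring, had a log2 change of -1.25, the decarboxylase Mvd of -0.996, the squalene synthase Fdft1 of -0.49 and Pmvk of -0.46.

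Of 21 genes of fatty acid and sphingolipid synthesis 5 rose and 4 fell (5 and 5 adjusted over the list alone, adjusted p = 0.464), with the transcription factor Srebf1 rising by 2.26 and the carboxylase Acaca at -0.86. In fatty acid oxidation 6 of 14 genes rose and 1 fell (adjusted p = 0.248), the latter being the brain carnitine palmitoyltransferase Cpt1c, at -1.08. The oxidative stress genes of the NRF2 response did not pass (7 rose and 2 fell of 18, 10 and 2 adjusted over the list alone, adjusted p = 0.0551), although the list passed by camera in several other settings. The quinone reductase Nqo1 rose by 1.57 and the cystine transporter Slc7a11 by 0.84, while the glutathione transferase Gsta4 fell at least 16.2-fold. In the cytosolic ribosome 0 of 28 genes passed in limma, adjusted over all probe sets or over the list alone (list adjusted p = 0.464 by camera).

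The measured genes of the interferon response were higher in old cells, with 8 of 11 rising and 1 falling (median 1.22, adjusted p = 0.0146, and adjusted p = 0.573 with an estimated correlation). Another 17 members were under the filter. Irf7, Mx1 and Bst2 were among them, at 2.14 on all 6 arrays, and Xaf1, which reached 5.25 on an old array and 2.28 on a young one. The antiviral gene Rsad2 rose by log2 2.54, Ifi35 by log2 3.37 and the GTPase Igtp at least 3.98-fold. Ifitm3, a membrane protein that blocks virus entry, had a log2 change of -3.72. The list did not pass without genes on chromosomes 10 and 11 (adjusted p = 0.208), a setting chosen after the values were seen. It leaves out 3 members, all of which rose, and of the 8 others 5 rose and 1 fell, with a median of 1.17 (quartiles 0.09 and 1.49) against 1.22 (quartiles 0.63 and 2.39) for all 11. Of 7 genes of antigen presentation 3 rose and 2 fell, and the list did not pass (adjusted p = 0.586, higher by camera's test and the median, with the mean below 0). Tapbp rose by log2 0.97 and the peptide transporter Tap1 at least 3.19-fold, while the class II gene H2-Eb1 fell at least 5.28-fold. Of 6 targets of NF-kB 2 rose and 1 fell (4 and 1 adjusted over the list alone, adjusted p = 0.197), the chemokine Cxcl10 rising by 2.45.

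Of 20 genes of the extracellular matrix and basement membrane 9 rose and 4 fell (10 and 5 adjusted over the list alone), and the list did not pass (median 0.49, adjusted p = 0.113). The collagen IV chains rose, Col4a2 at least 14.3-fold and Col4a1 by log2 2.60, while the protease Adamts1 had a log2 change of -2.01. Among 20 genes of intermediate filaments and the actin cytoskeleton 4 rose and 10 fell (4 and 11 adjusted over the list alone, adjusted p = 0.156). Anxa1 rose by 4.40 and S100a4 by 1.56, while Anxa2 had -2.38 and Tagln2 -2.11. In the BMP and TGF-beta pathway 4 of 13 genes rose and 6 fell (adjusted p = 0.46), the receptor Tgfbr2 rising by 2.74 and the receptor Bmpr1b at -2.06. In the Wnt pathway 5 of 14 rose and 1 fell (adjusted p = 0.46), the receptor Fzd9 rising by 2.06 and the secreted antagonist Sfrp2 at -1.49. In the Hedgehog pathway 5 of 7 rose and none fell (adjusted p = 0.197), among them the transducer Smo, by 1.06. Of 19 immediate early and growth factor response genes 5 rose and 9 fell (6 and 9 adjusted over the list alone, adjusted p = 0.216), with Egr2 at -1.37, Fosl2 at -1.22, Fos at -1.12 and the phosphatase Dusp4 rising by 2.70.

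**Figure D2:**
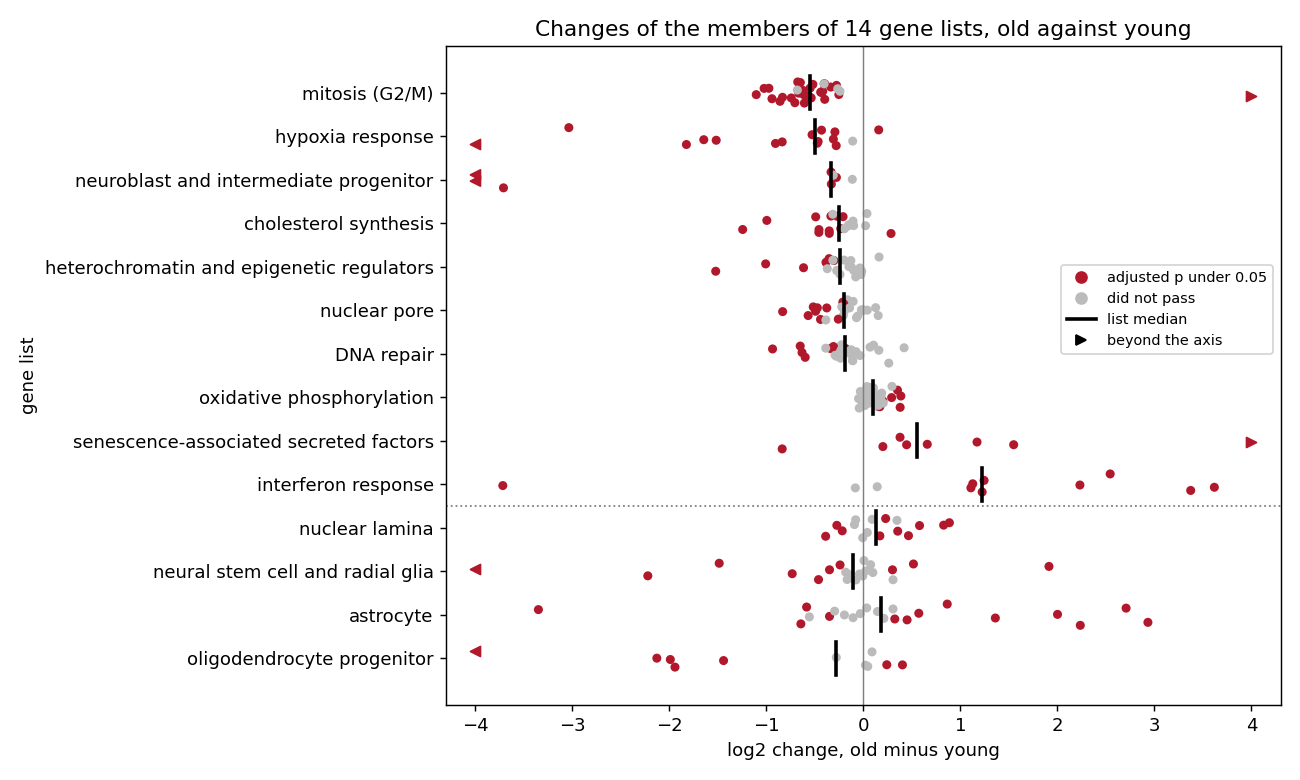
Log2 change, old minus young, of every measured member of 14 lists, each point 1 gene, red where its adjusted p was under 0.05 and grey otherwise, with the list median as a black bar. The 10 lists above the dotted line passed with the preset correlation and the 4 below it did not, and 7 points beyond log2 4 in size are drawn as arrowheads at the edge.

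Markers of other cell types that a preparation of neural stem cells could hold were mostly under the filter. Of microglia and macrophage genes 20 lay under it and 1 was measured, Cd68, with a mean of log2 3.67 in young and 5.07 in old cells. It did not pass in limma (adjusted p = 0.0697). Over the list alone it counts as passing, but with 1 gene that is the unadjusted limma p of 0.029. Of endothelial genes 14 lay under it and Flt1 was measured, with a log2 change of -1.22. Of choroid plexus genes 9 lay under it, among them Ttr at 2.14 on all 6 arrays, and Ecrg4 rose by 3.16. All 4 erythroid and all 10 complement genes named on the array were under the filter. Of the genes of pericytes and smooth muscle 11 lay under it, and the 3 measured ones fell. Of 5 measured genes of meningeal fibroblasts 2 rose and 1 fell (2 and 2 adjusted over the list alone, adjusted p = 0.727), with the collagen genes Col5a1 and Col6a1 rising by 3.55 and 2.20. Of 7 genes of ependyma and motile cilia 4 rose and 2 fell (adjusted p = 0.251), among them Foxj1, the master factor of motile cilia, at least 3.50-fold, and S100a6 at least 5.74-fold. Xist, the RNA of the inactive X chromosome, was at 2.14 on all 6 arrays, and of 3 measured Y-linked genes 1 rose (2 adjusted over the list alone), Eif2s3y by 0.19 (adjusted p = 0.0379), a call lost on leaving out any 1 array.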

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

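The setting without genes on chromosomes 10 and 11 was chosen after seeing the data and all others before. Of 160 named genes 155 passed in the reported fit, and 154 of these kept their direction in every setting run for them. Of the 155, 142 stayed past the threshold throughout and 13 were lost in at least one setting. The exception in direction was Septin6, with a log2 change of -0.031 on the mean of its probe sets, which disagree. The count of 7268 changed probe sets was between 5010 and 6838 when 1 array was left out, with 2768 to 3961 higher and 2177 to 3301 lower. It was 4359 on the mean of each gene's probe sets (2431 higher and 1928 lower), which tests fewer values, and 2162 with at least a 2-fold change as well (1258 higher and 904 lower). Again quantile-normalized or centred values moved the median change of all probe sets by less than 0.1. With a replicate block 5600 probe sets passed. Deviations of same-numbered arrays correlated at -0.16, -0.11 and 0.16, which gave no sign that the numbers pair the samples. With 3 arrays per age this cannot exclude pairing, and the labels do not say. The 10 lists became 9 to 12 on leaving out 1 array, 0 with an estimated correlation, where 2 had an unadjusted p under 0.05, and 32 with fry, which asks another question. For 3 lists that did not pass, the direction turned, and the cause was not tested. For the septins the adjusted p was then 0.732 with no filter, 0.907 after quantile normalization, 0.973 with array weights, 0.833 without genes on chromosomes 10 and 11, and 0.973 without young replicate 2 (0.835 to 0.973 on leaving out 1 array). For mature oligodendrocytes it was 0.719 with no filter, 0.973 with array weights, 0.958 without young replicate 2 (0.763 to 0.981 on leaving out 1 array) and 0.0011 with fry. For meningeal fibroblasts it was 0.919 with no filter. By camera 3 other lists that did not pass gained a call. Oxidative stress genes did so with no filter (adjusted p = 0.00148), after quantile normalization (0.0371), without young replicate 3 (0.0462), without old replicate 1 (0.0319, with 0.0319 to 0.130 on leaving out 1 array) and without genes on chromosomes 10 and 11 (0.0375). Oligodendrocyte progenitor genes did so with no filter (0.0286) and on the mean of each gene's probe sets (0.0482), and replication genes with no filter (0.0437) and without old replicate 1 (0.0238, with 0.0238 to 0.266 on leaving out 1 array). The call for secreted factors of senescence ended with no filter (adjusted p = 0.0507) and with an estimated correlation, with camera's adjusted p between 0.00517 and 0.573 over the settings. Signal near the GCRMA floor limits what can be said of dim genes, whose changes are bounds.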

Other observations

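Some large changes fell outside the rule for named genes and were picked after their values were seen. Tbx18, a transcription factor of mesenchymal and pericyte lineages, was higher in old cells by 6.08 on the log2 scale, and its other kept probe set was higher as well. Prrx1, another mesenchymal transcription factor, was at least 22.8-fold lower in old cells. Bcl11a, a transcription factor of developing neurons, was at least 24.8-fold lower, with its 2 other kept probe sets lower as well. The cell cycle kinase Cdk6 was at least 18.7-fold lower. Gene families that share a symbol stem were also tested as lists, again chosen after the data were seen. Of 153 families with at least 8 measured genes 3 passed by camera. Of 25 kinesins 13 fell and 2 rose (median -0.44, adjusted p = 0.0221), of 18 genes with the Nup stem 10 fell (median -0.24, adjusted p = 0.0282), and of 125 with the Tmem stem 49 rose and 8 fell (median 0.18, adjusted p = 0.0221). Each had an adjusted p = 0.978 with an estimated correlation. The Nup family shares genes with the nuclear pore list and the kinesins with the mitosis list, so these families are not separate findings.

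Among the tests reported here, those of pairs of arrays, hybridisation controls, RNA quality, genes with no other kept probe set, probe sets dropped by the filter, random and level-matched draws, other autosomes, the shift by level, chromosome segments, single arrays and the gap to replication genes were chosen only after the result was seen. The 6 arrays can be split in 10 ways into 3 and 3, too few for a share under 0.05. The real split gave 7268 changed probe sets and the highest other split 0 in limma, although up to 391 probe sets had an unadjusted p under 0.05 there. Only the real split, 1 of the 10, thus gave as many. In every other split both ages lie in each group, so their difference adds to the spread within groups and lowers the calls. The 0 is therefore no reference for the count without an age difference. For gene lists the real split gave 10 passing lists and 2 of the 10 splits gave as many, the highest other 11, for young replicates 1 and 2 with old replicate 1 against the rest. A mixed grouping of the arrays thus reached list calls too, but each such split has 2 arrays of one age in one group and 1 in the other. It carries part of the age difference, so its calls do not show what the preset correlation gives without one.

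The first pattern is the 148 genes that differed at least 16-fold. For 51 of them with another kept probe set, a faulty or cross-hybridising probe set is argued against, since 100% of those 66 probe sets changed at least 2-fold the same way, against 6.05% for genes that changed under 2-fold. The filter drops probe sets that are dim at both ages, which could not disagree there, and with these 65.1% of the 109 other probe sets of the 51 genes changed so. For the other 97 genes this stays open, as 53 have no other probe set on the array and 44 only dropped ones, 8 of 62 of which changed so. Random noise near the floor is argued against by pairs of arrays, since over all genes at most 2 differed at least 16-fold between arrays of the same age and at least 144 between arrays of different ages. For the 103 genes at least 16-fold apart with the 62.8% at their bound, a hybridisation difference of the controls' size was considered. The controls changed by at most -1.42, all 18 downward. Of these genes 42 rose and 61 fell by at least log2 4, apart from a fall of at least 10.3-fold against the highest old array. This argues against such a difference only if it acts alike at all levels. The controls were bright, with means of log2 13.24 in young and 12.28 in old arrays, so the response of dim probe sets was not tested. Handling of the cells or their RNA before hybridisation cannot be told apart from age, since it runs along with age and 1 of 3 measures of RNA quality parted the ages. Age may account for the 16-fold differences, as may the identity of the cell preparations, neither of which was tested.

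The second pattern is a small shift of 2 whole chromosomes. Among genes above log2 8 the median change was -0.17 on chromosome 10 and -0.16 on chromosome 11 relative to the other autosomes, and that of each of the other 17 autosomes, taken the same way, lay between -0.04 and 0.10. Neither random draws nor level-matched draws of genes were as low (permutation p = 1e-04 for both, the smallest that 10000 draws can give), and 16 of 16 segments along the chromosomes were lower, which argues against chance, gene level and a few regions. The 2 chromosomes were taken up after they were seen to be the lowest. The p is not adjusted for that choice, and the draws treat genes as independent. Within these limits the draws argue against array handling that acts on probe sets whatever their chromosome. Of the other autosomes 0 of 17 were shifted down by at least 0.5 of that amount, which adds little since the lowest chromosomes had been picked. A different mean copy number of these chromosomes in the 2 groups of cells may be a candidate explanation but stays open. Over all 510 and 811 kept genes of the 2 chromosomes, those of low, middle and high level were lower in 6 of 6 strata, by -0.34, -0.27 and -0.14 on chromosome 10 and by -0.21, -0.24 and -0.12 on chromosome 11. The shift thus varied with level, and low minus high was -0.19 (95% bootstrap interval over genes -0.32 to -0.03) and -0.09 (-0.20 to -0.001). Whether the arrays render a copy number difference alike at all levels was not tested, so this variation does not decide on it. An extra copy in all young cells would be a difference of log2 0.585, DNA was not measured, which age departs from 2 copies is open, and so are age itself, handling of the cells and effects of probe sequence, which were not tested.

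The third pattern is the lower level of mitosis genes in old cells. It does not rest on chromosomes 10 and 11, as the median over the 28 genes elsewhere was -0.57 (adjusted p = 1.56e-07), nor on 1 array, as the list passed without each of the 6. The fall was not equal over cell cycle genes, with a gap of -0.41 between the medians of mitosis and replication genes. Its permutation p was 1e-04 (one-sided, the smallest that 10000 reassignments of genes can give). The reassignments treat genes as independent, while the estimated correlations were 0.69 for mitosis and 0.57 for replication genes. This p thus does not measure the spread between samples, and the gap cannot decide whether fewer cells divided. A shift in the share of cells in mitosis may remain, as may handling of the cells or RNA and age, which were not tested, and with an estimated correlation the list did not pass (adjusted p = 0.589).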
